A study of Caenorhabditis elegans with 16 samples.

How the data were processed

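The series holds 8 mRNA and 8 small RNA libraries of whole day 1 adults of C. elegans strain JA1527, 4 of expressing and 4 of silenced sisters in each assay. Per the labels' protocols, mRNA libraries were made with SMART-Seq v4 and Nextera XT, a kit combination that does not mark the strand, and sequenced on a MiniSeq. Small RNA was treated with tobacco acid pyrophosphatase, so that small RNAs with a 5' triphosphate were captured as well, made into libraries with the NEBNext small RNA kit, size selected and sequenced on a HiSeq instrument. Per the submitters' processing notes, the tools were FastQC, cutadapt, Bowtie2, HTSeq and DESeq2. Their versions, roles and settings, the genome build and the annotation are not given in the sources used here.

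The deposited files held 1 whole-number read count per gene for each library, not normalized, in the layout that HTSeq writes. Each file ended in 5 tally entries that name no gene, and these stayed out of library sizes and tests. In the mRNA files, reads on no feature made up 49.9% to 50.3% of the reads either on genes or on no feature, and reads of low alignment quality 11.4% to 23.5% and unaligned reads 0.477% to 0.938% of all tallied. In the small RNA files, reads on no feature made up 34.1% to 57.6% of the same sum, unaligned reads 9.19% to 14.6% of all, and reads of low alignment quality 0. The files held 46778 mRNA and 45647 small RNA identifiers, of which 43818 and 43322 were matched to a symbol in the reference gene table, and counts on identifiers without a symbol were 0.723% of mRNA and 11.8% of small RNA counts. No coordinates are given, because the build of the counts is unknown, and the reference table was used for names, classes and which genes overlap. No sample column was left unused (0). Small RNA counts were summed per gene over all lengths, with a strand setting not given in the sources used here, so that microRNAs, piRNAs, small interfering RNAs and fragments of longer RNAs are not separated.

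Samples were grouped by the labels. The replicate number marks the litter of a mother, so replicates are separate litters. With the litter as a block, p-values measure how far the difference between sisters varies from litter to litter. Without the block, they measure the spread between libraries of the same sort, differences between litters included. The pairing was checked before the fits were compared, by correlating each library's deviation from its group mean across genes. Same-number libraries correlated at 0.331 to 0.829 in mRNA (other numbers -0.723 to 0.301) and at 0.215 to 0.437 in small RNA (other numbers -0.235 to -0.010), and each of the 8 libraries of both assays correlated best with its own number. The first principal component took 59.6% of the mRNA and 31.2% of the small RNA variance. No 2 libraries of the same sort and assay agreed within sampling noise (chi-square per degree of freedom 28.8 to 394).

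Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling with factors of 0.799 to 1.16 in mRNA and 0.853 to 1.13 in small RNA, filterByExpr by sort, Benjamini-Hochberg adjustment, threshold 0.05), silenced minus expressing. The design without the litter was the planned comparison, since the sources give no model, and the fit with the litter as a block was set beside it. Because the litters pair the samples, blocked values stand beside the others, and log2 changes, their standard errors and adjusted p-values of single genes are those of the blocked fit unless stated. Unblocked adjusted p-values of all named mRNA genes were over 0.05. CPM values are counts over the library's total on genes, without TMM factors, and log values used a prior count of 2. The filter left 10701 mRNA and 10077 small RNA genes. The 24 gene lists were tested with camera of limma 3.58.1 (preset correlation 0.01, lists with at least 3 tested genes), and with an estimated correlation and fry as alternatives. Shares of library counts were compared with an exact two-sided permutation test over 4 against 4 libraries. Changes in the assays were correlated over genes tested in both.

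Genes were named by a rule fixed before the data were examined: up to 12 per direction past the threshold without the block with a mean of at least 5 CPM, filled to 5 by the smallest p where fewer passed, and up to 6 per direction by size past the threshold with the block. The rule also takes mex-5, his-58, tbb-2, unc-119 and hsf-1, up to 3 members per list by p with a mean of at least 1 CPM, of which up to 2 were taken, and genes past the threshold in both assays (0 here). The genes mlc-2, unc-27, mlc-3, col-19, col-8, cnc-2 and nlp-30, which passed with the block in lists with up to 5 such members, were named after their values were seen, as were egl-21 and C44B11.6 and the genes set out for litter 4.

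Alternatives were the block, DESeq2 1.42.0 size factors, upper-quartile and total-count scaling, no filter, a filter of 10 CPM in 4 libraries, DESeq2, limma-voom, an adjusted p of 0.1, and leaving out each library or litter. The medians of lists per litter are medians over genes of the difference in TMM-scaled log2 CPM of its 2 libraries. The fits were tested on simulated counts drawn from the real means, library sizes and litter differences, with dispersions estimated with the block. Genes were drawn independently of each other. The simulated counts thus follow the model of the blocked fit, which favours it, and false calls may be more frequent in real data. Over 10701 mRNA genes, of genes changed by 1 or 2 on the log2 scale the unblocked fit recovered 0% and 21.0% and the blocked fit 68.0% and 89.0%. Over 10077 small RNA genes it was 9.00% and 66.0%, and 56.0% and 80.0%. False calls were 0 of 21 and 8 of 165 in mRNA, and 1 of 76 and 13 of 149 in small RNA, without and with the block. Libraries carry no molecular identifiers, so the limit given for a count of 0, 3 counts, covers counting error only.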

Results

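RNA was measured in Caenorhabditis elegans of strain JA1527, in which an mCherry transgene is expressed in some animals and silenced in others. Per the labels, 4 mothers that expressed mCherry laid eggs on plates of their own for 8 h at 20 °C. The genetically identical progeny of each mother were sorted by fluorescence as adults on day 1. The brightest 25% (expressing sisters) and the dimmest 25% (silenced sisters) of each of the 4 litters were collected as whole animals. The 8 sorted samples gave 8 mRNA libraries and 8 small RNA libraries, so that each assay set 4 silenced against 4 expressing samples. Reads counted on genes numbered 10433874, 10212451, 8965623 and 7254707 in the expressing and 9265187, 9191210, 9033480 and 6184364 in the silenced mRNA libraries of litters 1 to 4. The small RNA libraries held 10105854, 9159256, 8378089 and 5476510 in expressing and 6845327, 10452004, 19106994 and 4459219 in silenced sisters. Between 14138 and 15918 genes had a count in an mRNA library and between 13194 and 16328 in a small RNA library. Libraries of the same litter deviated together in both assays, so the comparison within litters is given beside the comparison without them.

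The mRNA libraries address which endogenous transcripts differ between sisters that silence and sisters that express the same transgene. Within litters, 5 of the 14 tested genes of the adult cuticle list and 5 of the 20 of the body-wall muscle list rose in silenced sisters, and 4 of the 31 of the innate immunity list fell. As sets the cuticle and muscle lists did not pass with the block when the correlation was estimated (camera adjusted p = 0.479 each with an estimated correlation), and the 5 muscle calls were lost without litter 1. The 6 largest increases among genes with at least 5 CPM (library-size-scaled counts) on average and an adjusted p under 0.05 were all of cuticle collagen genes. The mRNA of col-93 (WBGene00000668) rose from 126.5 ± 35.9 to 512.9 ± 170.5 CPM (mean ± SD, n = 4 and 4). Its log2 change was 2.06 with a standard error of 0.22 (edgeR, Benjamini-Hochberg adjusted p = 6.99e-04). The mRNA of col-124 (WBGene00000698) rose from 333.5 ± 79.4 to 1042 ± 470.5 CPM, by 1.63 ± 0.20 (SE) on the log2 scale (edgeR, Benjamini-Hochberg adjusted p = 0.00254). The other 4 were col-34 and col-153 (log2 change 1.56 each), col-20 (1.38) and col-159 (1.37). Among the decreases, Y41G9A.5 (WBGene00021529) had the smallest adjusted p (2.35e-04, edgeR, Benjamini-Hochberg). It went from 44.1 ± 18.6 to 12.5 ± 7.34 CPM, a log2 change of -1.81 with a standard error of 0.17. The largest decreases by the same rule were in F57H12.6 (log2 change -2.82, SE 0.49) and ora-1 (-2.06, SE 0.37), with litter 3 changing least in both. The others were scl-5, a gene of the secreted SCP family (-1.69), F08D12.3 (-1.67) and F16B4.7 (-1.57). T22B7.7 went from 100.1 ± 40.5 to 37.2 ± 8.80 CPM (log2 change -1.31, SE 0.16), W06H8.2 from 18.8 to 9.10 CPM (-0.98) and the F-box gene fbxb-7 from 48.1 ± 10.9 to 25.6 ± 3.77 CPM (-0.84). All of the genes named so far passed the threshold within litters, and each moved the same way in 4 of 4 litters. Leaving out any litter kept the calls of col-93, col-124 and Y41G9A.5 (edgeR, largest adjusted p = 0.0136, 0.0329 and 0.00957). The calls of F57H12.6, ora-1, F08D12.3, F16B4.7 and W06H8.2 were lost without litter 1 and without litter 2 (edgeR adjusted p = 0.0614 to 0.205), that of col-153 without litter 1 (0.204) and litter 4 (0.0598), that of F16B4.7 also without litter 4 (0.0579) and that of fbxb-7 without litter 2 (0.0682).

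**Figure D1:**
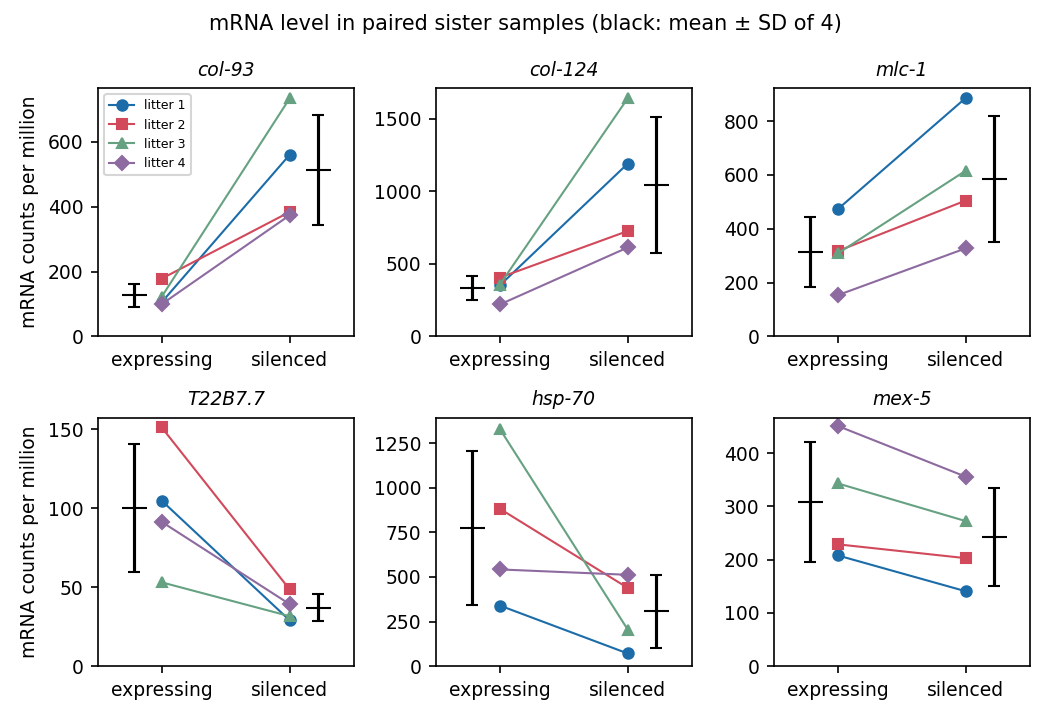
Counts (CPM) of col-93, col-124, mlc-1, T22B7.7, hsp-70 and mex-5 in each mRNA library, with expressing on the left, silenced on the right, a line joining the libraries of a litter, and the mean ± SD of 4 libraries. The lines of col-93 climb in 4 of 4 litters, from a mean of 126.5 to 512.9 CPM, and those of T22B7.7 descend in 4 of 4, from 100.1 to 37.2 CPM.

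With the litter as a block, 121 of 10701 genes tested passed an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 88 higher and 33 lower in silenced sisters. The higher genes had a median log2 change of 0.93 (0.59 to 2.34) and 87 of the 88 were higher in every litter. The lower genes had a median of -1.19 (-2.82 to -0.62) and 32 of the 33 were lower in every litter. Without the block, edgeR called 0 of the same 10701 genes, with 128 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 3, the collagen genes col-93, col-124 and col-125, the last named after its value was seen. The edgeR adjusted p of col-93 was then 0.442. The share of higher genes among the blocked calls was 72.7% with TMM scaling, 84.3% with upper-quartile scaling (91 higher and 17 lower) and 59.1% with total-count scaling (65 higher and 45 lower). Leaving out litter 1, 2, 3 or 4 gave 24, 52, 205 and 78 blocked calls, and ended the calls of 18, 12, 1 and 7 of the named genes. The 2 libraries of litter 4 stood apart from the rest. Vitellogenin mRNAs took 20.8% and 23.3% of their counts, against 1.10% to 3.23% elsewhere. Without that litter 62 of the 121 genes were still called.

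Of the lists of genes fixed before the data were examined, the adult cuticle list had the largest median change in mRNA. All 14 of its tested members were higher in silenced sisters (median log2 change 0.73). Of these 5 rose within litters, 13 rose when adjusted over the list alone, and 7 passed over the list alone without the block. Besides col-93 and col-124, the members that rose were col-179 (116.9 to 274.1 CPM, log2 change 1.35), col-8 (1.07) and col-19, a collagen of the adult stage (375.4 to 743.4 CPM, 1.03). The call of col-19 was lost without litter 1 (edgeR adjusted p = 0.148). In the list of body-wall muscle genes 16 of 20 were higher (median 0.46), 5 rose and 9 rose when adjusted over the list alone. These 5 were the myosin light chain genes mlc-1 (313 ± 130.5 to 583.5 ± 234.1 CPM, log2 change 0.97, SE 0.15), mlc-2 (0.88) and mlc-3 (0.78), the troponin T gene tnt-2 (0.94) and the troponin I gene unc-27 (0.84). All 5 calls were lost without litter 1 (edgeR adjusted p = 0.0614 to 0.204), and that of mlc-3 also without litter 2 (0.0747) and litter 4 (0.0506). Of the neuronal genes 18 of 20 were higher (median 0.51), with 0 called over all genes and 7 when adjusted over the list alone. The gene sbt-1, which encodes a partner of a neuropeptide-processing protease, went from 46.5 to 75.4 CPM (log2 change 0.68, edgeR, Benjamini-Hochberg adjusted p = 0.0730). For unc-25, the enzyme that makes GABA, the log2 change was 0.59. Ribosomal protein genes were higher in 75 of 77 cases averaged over litters (median 0.17), with 0 called, but the medians of litters 1 to 4 were 0.12, 0.23, 0.65 and -0.35. Of the intestinal genes 13 of 18 were higher (median 0.14, and -0.13 in litter 3), with 0 called. The ribosomal genes rpl-11.2 (0.51) and rpl-1 (0.29), the lipase gene lipl-4 (0.51) and the protease gene asp-1 (0.42) did not pass.

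The medians of the oocyte, germ cell, small RNA machinery and Argonaute lists were below 0. Of 28 oocyte and maternal genes 26 were lower in silenced sisters (median log2 change -0.28), of 32 germ cell and meiosis genes 27 (-0.14), of 55 genes of the small RNA machinery 43 (-0.17) and of 15 Argonaute genes 12 (-0.18). With the block these 4 lists in turn had camera adjusted p = 0.481, 0.479, 0.481 and 0.490 with an estimated correlation. Over all genes 0 of their members were called by edgeR, and 1 small RNA machinery gene was lower when adjusted over the list alone. Examples below the threshold were the maternal RNA-binding protein genes mex-6 (195.1 to 136.8 CPM, -0.47) and mex-3 (149.3 to 109 CPM, -0.42) and the RNA interference genes rde-11 (25.1 to 17.4 CPM, -0.48) and eri-7 (-0.72). Others were the Argonaute genes nrde-3 (-0.52) and alg-1 (-1.01), the pairing-centre gene zim-2 (-0.24) and the meiotic cohesin gene coh-3 (-0.37). Heat shock and chaperone genes were lower in 22 of 28 cases (median -0.17). The inducible chaperone gene hsp-70 fell from 773.8 ± 433.3 to 307 ± 204.5 CPM, a log2 change of -1.45. In contrast hsp-12.3, of the small heat shock family, rose from 70.1 to 139.1 CPM (1.10). The call of hsp-70 was lost without litter 1 (edgeR adjusted p = 0.232) and litter 2 (0.0767), with upper-quartile scaling (0.0520) and with DESeq2 (0.115), and that of hsp-12.3 without litter 1 (0.0543). When adjusted over the list alone, 2 chaperone genes were higher and 4 lower. In the innate immunity list 4 of 31 genes fell. They were the infection-response genes irg-4 (431.6 ± 76.3 to 252.7 ± 29.5 CPM, log2 change -0.70) and F55G11.2 (-0.76) and the epidermal antimicrobial peptide genes cnc-2 (-1.19) and nlp-30 (-0.94). The calls of irg-4, F55G11.2 and nlp-30 were lost without litter 1, 2 or 4 (edgeR adjusted p = 0.0649 to 0.295) and with upper-quartile scaling (0.0520 to 0.0608), and that of F55G11.2 also without litter 3 (0.0548). The list as a whole had 17 members higher and 14 lower, with a median of 0.12 and a mean of -0.01, and its camera direction was lower without the block and higher with it. Adjusted over the list alone, 6 were higher and 8 lower. In the list of DAF-16 targets 14 of 20 were higher (median 0.17) and 2 rose, hsp-12.3 and pck-1, which encodes a gluconeogenic enzyme (16.9 to 28.6 CPM, 0.81). The call of pck-1 was lost without litter 1 (edgeR adjusted p = 0.194), 2 (0.0503) and 4 (0.166). Adjusted over the list alone, 5 were higher and 2 lower.

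As sets against all other genes, 9 of 23 lists passed camera with a preset correlation of 0.01 without the block, and 11 with the litter as a block. Leaving out single libraries or litters gave 5 lists (without silenced library 1) to 13 (without silenced library 4). Higher in both fits were adult cuticle (camera adjusted p without and with the block 5.82e-25 and 1.01e-18), body muscle (1.57e-06 and 2.49e-09), neurons (7.58e-04 and 4.00e-06), ribosomal proteins (7.58e-04 and 1.00e-04) and intestine (0.0217 and 0.0237). In the same order and without the block, these 5 lists had adjusted p = 0.103, 0.137, 0.656, 0.813 and 0.656 with an estimated correlation. In all 0 lists passed camera with an estimated correlation, with 3 without and 0 with the block at an unadjusted p under 0.05. Lower in both fits were oocyte and maternal genes (1.03e-04 and 1.16e-07), germ cells and meiosis (0.00884 and 0.00105) and the small RNA machinery (0.00884 and 5.43e-04), with adjusted p = 0.656, 0.679 and 0.813 with an estimated correlation. The DAF-16 list passed without the block (0.00884, and adjusted p = 0.137 with an estimated correlation) but not with it (0.0673). The Argonaute list (lower, 0.113 and 0.00670), the heat shock list (lower, 0.113 and 0.0101) and the intracellular pathogen response (higher, 6 of 7 genes, median 0.32, 0.0697 and 0.0470) passed only with the block, with adjusted p = 0.490, 0.481 and 0.479 with an estimated correlation. The last list did not pass with the block and DESeq2 size factors (camera adjusted p = 0.0542), and its median in litter 4 was -0.46. In it 0 genes were called, 1 was higher when adjusted over the list alone, and the ubiquitin ligase genes cul-6 (0.85) and skr-3 (0.65) stood below the threshold. Fry, which asks whether the genes of a list move on balance one way, called 0 lists in either fit, with 3 lists without and 7 with the block at an unadjusted p under 0.05.

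**Figure D2:**
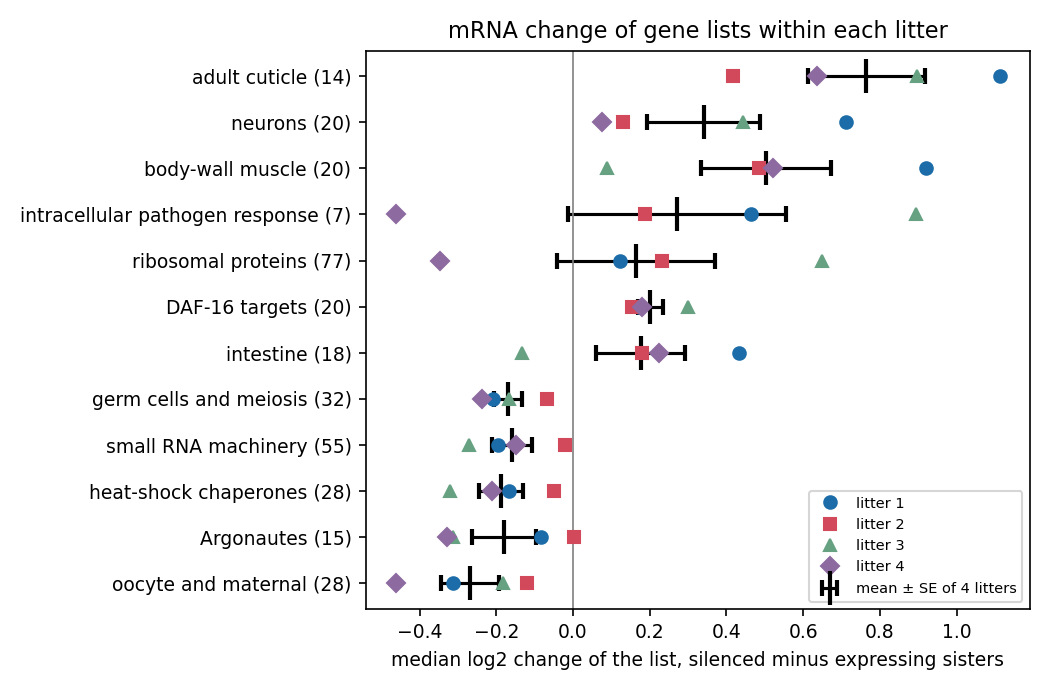
Median log2 change of silenced minus expressing mRNA libraries over the tested genes of 12 lists, with 1 point per litter and the mean ± SE of the 4 litters; the number of genes tested is in brackets. The adult cuticle, neuron and body muscle medians lie to the right of 0 and the oocyte median, -0.28 over all litters, to the left.

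The remaining lists did not pass. Medians were -0.10 for mitochondrial and endoplasmic reticulum stress (8 of 23 higher), 0.12 for moulting and the larval cuticle (9 of 13 higher), 0.07 for oxidative and xenobiotic responses (17 of 30 higher), -0.31 for vitellogenins (0 of 6 higher) and -0.09 for sperm genes (1 of 5 higher). The vitellogenin median was 0.30, -0.07, -1.54 and 0.06 in litters 1 to 4, and -0.03 in the fit without the block. Medians were 0.05 for early zygotic genes (8 of 13 higher), 0.05 for histones (20 of 28 higher) and 0.07 for piRNA loci (19 of 32 higher), and the sign of these 3 medians changed with the scaling of the libraries. The pharynx list (-0.13, 1 of 3 higher) had a camera direction of higher without the block and lower with it, and the loci known as targets of endogenous small interfering RNAs (5 of 11 higher, median -0.12, mean -0.02) had lower without and higher with it. None of these 10 lists had a member called over all genes. Adjusted over the list alone, 1 sperm gene was higher, and 3 of the known small RNA targets were higher and 2 lower. Only 8 identifiers were matched to a microRNA symbol in the mRNA libraries, and 1 of them was tested. As shares of all counts, body muscle genes took 1.13 ± 0.255% of expressing and 1.70 ± 0.435% of silenced libraries (mean ± SD, n = 4 and 4), higher in 4 of 4 litters (exact two-sided permutation p = 0.0571, adjusted 0.857). Oocyte and maternal genes took 2.63% and 2.22%, lower in 4 of 4 litters (exact permutation p = 0.114), and genes with a col- symbol 3.00% and 4.52%, higher in 4 of 4 (exact permutation p = 0.171). By exact permutation 0 of 15 mRNA shares passed adjustment and 0 had an unadjusted p under 0.05. The smallest p that 4 against 4 libraries can give is 0.0286, and 0.125 for sign flips within litters.

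The strain's transgene is generally described as holding the mex-5 promoter, the histone gene his-58 and the tbb-2 3' end, with an unc-119 gene as marker. Reads of mCherry itself were not analysed here, so the silenced and expressing states rest on the fluorescence sort and were not checked in the RNA counts. The endogenous mex-5 mRNA stood at 307.8 ± 112.5 CPM in expressing and 243 ± 92.5 CPM in silenced sisters, lower in 4 of 4 litters (log2 change -0.30, SE 0.14, n = 4 and 4; edgeR with the block, Benjamini-Hochberg adjusted p = 0.354). The tbb-2 mRNA was lower in 4 of 4 litters by a similar amount (496.6 and 409.9 CPM, -0.22, edgeR adjusted p = 0.509), and unc-119 stood at 3.97 and 4.02 CPM (0.10). The histone gene symbol his-58 was matched to 2 identifiers, WBGene00001932 and WBGene00001940, both at or under 0.588 CPM in every mRNA library and not tested. Identifiers of other histone genes, such as his-62 (WBGene00001936) and his-71 (WBGene00001945), rise in step with the symbol number. WBGene00001932 follows that order and WBGene00001940 does not, so the symbol of WBGene00001940 is doubtful. The mRNA of hsf-1, the heat shock transcription factor, stood at 29.5 and 24.1 CPM, lower in 3 of 4 litters (-0.31, edgeR adjusted p = 0.392). None of these fixed genes passed. Reads or small RNAs of a transgene part that has the sequence of an endogenous gene could not be separated from those of that gene. Reads of a gene and of an overlapping gene could not be separated either. Of 49 named mRNA genes with annotation 13 overlap another gene, among them col-93 (dhc-4), col-124 (qns-1), col-19 (hrg-11.4), mlc-1 (slc-17.1) and hsp-70 (uggt-2). Collagens, F-box genes and the near-identical mlc-1 and mlc-2 belong to families that can share reads, so their single values are uncertain.

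The small RNA libraries address which genes are templates or targets of different amounts of small RNA in the same sisters. A short noncoding locus, K08B5.4 (WBGene00195573), had small RNA counts in each expressing library (300.6, 258.4, 74.7 and 207.2 CPM) and 0 in each silenced library. It was called without the block and with it (edgeR, Benjamini-Hochberg adjusted p = 0.0102 and 3.57e-04). Pooled over the libraries, 7166 counts (216.4 CPM) stood against 0. With the 3 counts that 0 allows over the pooled silenced libraries (0.0734 CPM) it was at least 2947-fold lower. Leaving out expressing library 2 ended its unblocked call (edgeR adjusted p = 0.0516). Limma-voom did not call it without the block (adjusted p = 0.137) but did with it (1.87e-04). The locus overlaps K08B5.1 and a tRNA gene, K08B5.t2, so the transcript of origin is uncertain. Within litters, small RNAs of WBGene00013056, for which no symbol was matched, rose from 36.8 ± 14.9 to 98.1 ± 41.1 CPM (log2 change 1.30, SE 0.09, n = 4 and 4, edgeR adjusted p = 0.00343). Those of Y39A1A.9 fell from 34.0 ± 20.0 to 13.4 ± 6.82 CPM (-1.41, SE 0.14, edgeR adjusted p = 0.0324), a call lost on leaving out any litter (edgeR adjusted p = 0.0646 to 0.206). Small RNAs of the methyltransferase-family gene set-3 (44.1 and 77.8 CPM, log2 change 0.70) and of Y116A8C.9 (36.2 and 63.7 CPM, 0.71) were higher without passing (edgeR adjusted p = 0.0671 each), as were those of Y62E10A.20 (0.64) and WBGene00017391 (2.13). With the block, set-3 and Y116A8C.9 did pass with the strict filter (edgeR adjusted p = 0.0445 each), over protein-coding genes alone (0.0181 and 0.0188), with limma-voom (0.0266 and 0.0426), with DESeq2 and with no filter. They did not pass without any one litter (edgeR adjusted p = 0.0986 to 0.328). Y62E10A.20 passed with DESeq2 and the block (0.00764) and with no filter, and WBGene00017391 with no filter. F54F7.12 (14.1 and 0.327 CPM), B0244.13 (35.1 and 0.720 CPM), F22G12.9 (65.5 and 7.94 CPM) and C05G6.5 (16.8 and 1.62 CPM) were lower without passing. With the block F54F7.12 passed with limma-voom (adjusted p = 0.0266), B0244.13 without litter 3 (edgeR, 0.00639) and all 4 with no filter. The first 3 overlap tRNA genes and the last an snRNA gene.

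**Figure D3:**
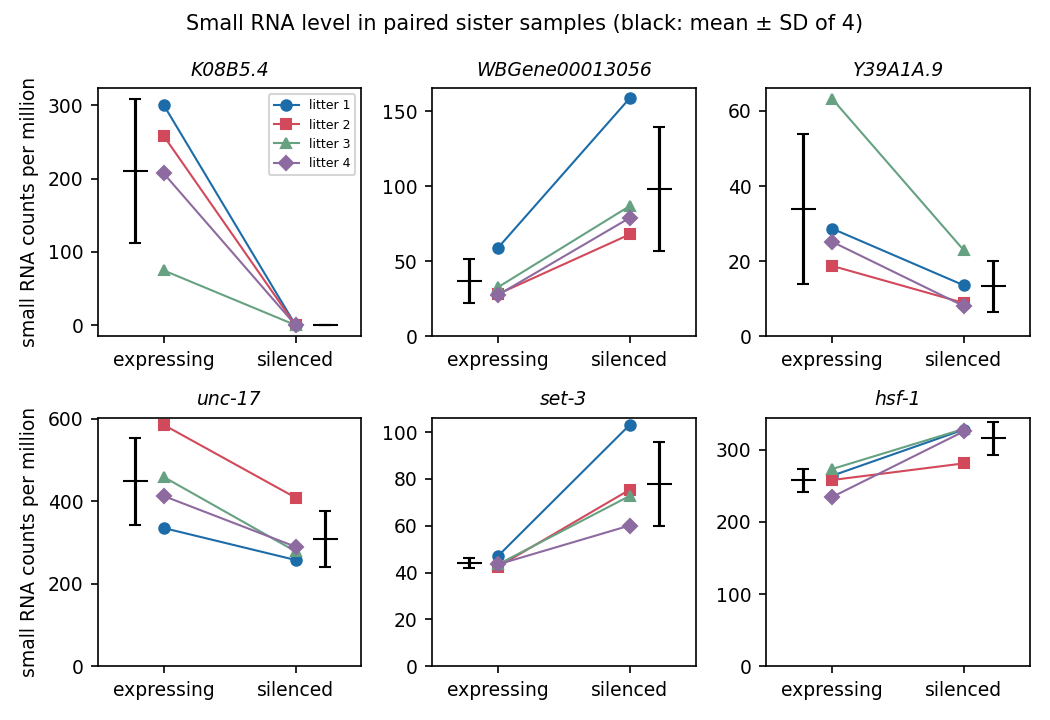
Small RNA counts (CPM) of K08B5.4, WBGene00013056, Y39A1A.9, unc-17, set-3 and hsf-1 in each library, with expressing on the left, silenced on the right, a line joining the libraries of a litter, and the mean ± SD of 4 libraries. K08B5.4 ends at 0 in each silenced library, and hsf-1 stands at 257.5 ± 16.6 CPM in expressing and 316 ± 23.2 CPM in silenced libraries.

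In all, 1 of 10077 genes passed in the small RNA libraries without the block (edgeR, Benjamini-Hochberg; 340 at an unadjusted p under 0.05), and 3 passed with the litter as a block, 1 higher and 2 lower. DESeq2 called 2, K08B5.4 and WBGene00017391, and limma-voom 0 without the block. The count without the block was 0 without expressing library 2, 3 without silenced library 2 and 2 without silenced library 3, and with the block it was 2, 4, 5 and 3 without litters 1 to 4. With the block, total-count scaling, which moved the median of all small RNA genes by 0.10 on the log2 scale, called 2 genes (1 higher, 1 lower) and not Y39A1A.9. The size factors of DESeq2 with the block gave 6 calls (1 higher, 5 lower). The blocked count depended far more on the method and the filter. It was 226 with DESeq2, 25 with limma-voom, 15 with the strict filter, 27 over protein-coding genes alone and 459 with no filter.

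No list of genes passed camera in the small RNA libraries, with 0 of 21 lists by either fit and 5 at an unadjusted p under 0.05 in each. Fry (limma) with the block called 2 lists at an adjusted p of 0.0320 each. Small RNAs of intestinal genes were higher for 8 of 11 (median log2 change 0.41) and those of neuronal genes lower for 9 of 13 (median -0.15). Without the block fry called 0 lists and had 1 at an unadjusted p under 0.05, and with an estimated correlation 0 passed. The 2 named intestinal members were pgp-1, a drug transporter gene (1.04), and cpr-1, a protease gene (0.43), and neither passed. Small RNAs of unc-17, the vesicular acetylcholine transporter, went from 447.8 ± 104.8 to 308.5 ± 68.1 CPM, lower in 4 of 4 litters (log2 change -0.63, SE 0.08, n = 4 and 4, edgeR adjusted p = 0.0544). With the block unc-17 passed with DESeq2 size factors (edgeR, 0.0492), the strict filter (0.0246), limma-voom (0.0124), DESeq2 and no filter, and over protein-coding genes alone (0.0122), but not without any one litter (0.0986 to 0.206). It passed when adjusted over the list alone, as did egl-21 (lower) and ida-1 (27.1 and 39.5 CPM, 0.44). Both ida-1 and pgp-1 overlap tRNA genes and unc-17 overlaps cha-1, so the transcripts of origin of these small RNAs are uncertain. Of 17 named small RNA genes with annotation 10 overlap another gene. The oocyte list (21 of 26 lower, median -0.13) and the intestine list had the same adjusted p by camera (limma) with the block (0.0510). With the block and DESeq2 size factors, camera called the oocyte and intestine lists (adjusted p = 0.0419 each), which with TMM scaling had adjusted p = 0.891 and 0.680 with an estimated correlation. Median log2 changes of the other lists were 0.19 for mitochondrial and endoplasmic reticulum stress (16 of 23 higher, and 1 of the lower genes passed when adjusted over the list alone), 0.15 for known small RNA targets (10 of 16 higher, 1 of them when adjusted over the list alone, C44B11.6) and 0.13 for piRNA loci. They were 0.07 for vitellogenins, 0.06 for early zygotic genes (mean -0.10), 0.04 for oxidative responses, 0.03 for Argonautes and 0.01 for germ cells. They were -0.02 for the small RNA machinery, sperm and innate immunity, -0.03 for heat shock and for histones (mean of histones 0.00), -0.04 for moulting (2 genes lower when adjusted over the list alone), -0.05 for ribosomal proteins, -0.12 for DAF-16 targets, -0.19 for body muscle and -0.20 for the intracellular pathogen response, in which 2 genes were lower when adjusted over the list alone. The cuticle, pharynx and microRNA lists had too few tested genes (0, 1 and 1). Only 7 identifiers were matched to a microRNA symbol, so this list does not show how much microRNA the libraries held.

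Among the fixed genes, small RNAs of hsf-1 were higher in 4 of 4 litters (log2 change 0.20, SE 0.09, n = 4 and 4, edgeR adjusted p = 0.444). Those of mex-5 stood at 126.9 and 120.9 CPM (-0.19, edgeR adjusted p = 0.513). Those of tbb-2, at 206.9 CPM in expressing sisters, were lower in 4 of 4 litters (-0.33, edgeR adjusted p = 0.386), and those of unc-119 stood at 65.5 and 66.2 CPM (-0.09). The his-58 identifier WBGene00001932 (2.27 and 1.88 CPM, -0.41) did not pass. Nor did WBGene00001940, for which the symbol his-58 is doubtful (4.77 and 9.98 CPM, 1.91). With the block and no filter, which called 459 genes, WBGene00001940 (edgeR adjusted p = 1.88e-04) and tbb-2 (0.0488) did pass. Neither passed in any other run with the block that tested it. The log2 differences of WBGene00001940 in litters 1 to 4 were 4.36, 4.17, 0.17 and -0.13, so its rise rested on litters 1 and 2. Small RNA counts on piRNA loci took 0.0775 ± 0.00880% of expressing and 0.0987 ± 0.00547% of silenced libraries (mean ± SD, n = 4 and 4), higher in 4 of 4 litters, with the smallest exact two-sided permutation p that the design allows (0.0286, adjusted 0.257). This holds for the share of all counts. With TMM scaling, the median log2 changes of the 62 piRNA loci that passed the filter were 0.69, 0.16, -0.12 and -0.04 in litters 1 to 4. Protein-coding genes took 71.2% of expressing and 73.0% of silenced libraries. By exact permutation 0 of 9 shares passed adjustment, and 1 had an unadjusted p under 0.05.

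The assays were then set against each other, to ask whether genes whose small RNAs differed also differed in mRNA. Across 7680 genes tested in both, the log2 changes had a Spearman correlation of 0.0125 and a Pearson correlation of 0.0285. Genes are not independent replicates, and flipping the sorts within litters gave Spearman values with an SD of 0.0483. The Spearman correlation was -0.0205 without litter 4 and 0.0651 without litter 3. Of the 88 genes with higher mRNA, 17 were tested in both assays, and their small RNAs were higher for 10 and lower for 7 (median 0.13). Of the 33 with lower mRNA, 6 were tested in both, 3 higher and 3 lower (median -0.07). By edgeR with the block, 0 genes passed in both assays. At an unadjusted p under 0.05 in both there were 92, with 48 moving the same way and 44 opposite ways (Fisher's exact test, two-sided p = 0.672).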

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

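The 3 tests on K08B5.4, the margin of the litter test below, and the splits of the libraries for the counts of genes and for the correlation between assays were chosen only after the results were seen. The other tests of this part had been set out before they were run. Those on cuticle and muscle genes concern a pattern picked from these results, so they were set out after that pattern was seen.

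Within litters 5 of 14 adult cuticle and 5 of 20 body muscle genes rose in silenced sisters (4 muscle genes were lower), and neither list passed camera with an estimated correlation (adjusted p = 0.479 each with an estimated correlation) or fry (0.127 each). A lower share of germline tissue in silenced samples would lower germline lists. The medians of the oocyte and germ cell lists were below 0 in 4 of 4 litters. A lower share would also raise somatic lists alike. The median change of muscle genes exceeded that of intestinal genes in 4 of 4 litters, by 0.328 on average (SE 0.0563, n = 4), so these lists did not rise alike. The muscle list was taken because it had risen, which favours such a difference. The test therefore cannot decide, and a lower germline share stays open. A difference in library size is argued against by thinning all libraries to the smallest total, which kept 92 of the 121 genes (76.03%). Sisters at different points of adult development remain a candidate explanation that was not settled. Over the 121 genes the correlation with the axis that separates litter 4 from the rest was -0.0780 (SE 0.0921, which treats genes as independent). This was under the bound of 0.2 set before the correlation was run, but within 2 standard errors of that bound. Over all 10701 genes the correlation was -0.45. The margin was required because the genes called go mostly in 1 direction. On this axis, the log2 difference of litter 4 from the other litters, the median was -1.10 over the called genes higher in silenced sisters. Over the called lower genes it was -0.19. Whether this axis follows development is not known, since the libraries of litter 4 also differed in read quality, so the correlation cannot decide. Development, library quality and silencing cannot be told apart here for these genes, and a biological effect of the silenced state stays open and untested.

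Small RNA counts on K08B5.4 were present in 4 of 4 expressing libraries and at 0 in 4 of 4 silenced libraries. Low depth is argued against, since the lowest expressing level would give 333.2 counts in the shallowest silenced library. In all, 10 small RNA loci were either on (at least 20 CPM) or off (at most 2 counts) in every library, with each state in at least 2 libraries, and 9 of these 10 followed other lines than the sort, with 10 distinct patterns, against 0 such loci in the mRNA libraries. The rule leaves out loci with a value between these levels. Among those left out, B0244.13, F54F7.12 and F22G12.9 overlap tRNA genes and were lower in silenced sisters in 4 of 4 litters. These had been named for their small p-values, so they do not show how often such loci follow the sort. All 9 short noncoding loci among the 10 overlap a tRNA gene, and of the 7 that passed the filter 7 do, against 127 of the 311 other short noncoding loci that passed it (40.8%, Fisher's exact test, two-sided p = 0.00215). Uneven capture or assignment of tRNA reads may therefore account for K08B5.4 without the sort, and an effect of silencing on this locus was not separated from it.

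The other splits of the 8 libraries bear on the counts. Where the real count is 0, every split reaches it whatever the data, so the splits decide nothing: 35 of 35 for mRNA genes without the block (highest other 0) and 35 of 35 for small RNA lists (highest other 7). Without the block, chance cannot be excluded for small RNA genes, where 7 of 35 splits gave at least the real 1 and the highest other, 6, came from a split that kept litters together; of the 8 splits that part all 4 pairs, the others gave 0. For lists, 10 of 35 splits gave at least the real 9 in mRNA (highest other 14, and 11 among splits that keep litters together), while the other splits that part all 4 pairs reached 7 at most. With the litter as a block there are 8 splits, too few for a share under 0.05. The real value and the highest other split were 121 and 0 for mRNA genes, 3 and 2 for small RNA genes, and 11 and 10 for mRNA lists, and in each of these 1 of 8 splits was as large as the real one, the real one itself. For the correlation between assays, taken from the changes without the block over the same 8 splits, they were 0.0125 and 0.110, and 4 of 8 were as large in absolute size.

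Single libraries stood apart from the other 3 of their group by Dixon's test in 20 of 202 groups examined, where chance flags about 1 in 20 groups, or 10.1 here. In the mRNA libraries of litter 4, 8 values did so. The silenced library held 6.184 M counts on genes (others 9.033 M to 9.265 M), 23.55% reads of low alignment quality (others 11.35% to 13.01%) and 38.1% reads on no feature (others 43.16% to 43.85%), and alg-1 stood at 7.115 CPM in it (others 1.403 to 2.067). The 10 most abundant genes took 28.65% of the expressing library (others 13.6% to 14.66%) and 30.2% of the silenced library (others 14.52% to 15.04%). Vitellogenins took 20.82% of the expressing library (others 1.352% to 3.228%) and 23.32% of the silenced library (others 1.104% to 1.504%). In mRNA of litter 1, expressing sisters had col-179 at 59.42 CPM (others 130.8 to 143.9), unc-25 at 10.26 (others 4.798 to 5.354) and lipl-4 at 21.28 (others 7.995 to 10.26), and silenced sisters had asp-1 at 761 CPM (others 520.2 to 539.3).

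In small RNA, the expressing library of litter 1 had a piRNA share of 0.06439% (others 0.08096% to 0.08312%), WBGene00013056 at 58.88 CPM (others 27.57 to 32.7) and 12.78% of counts on F31C3.14 and F31C3.16, which overlap ribosomal RNA genes (others 0.4108% to 0.6683%). The silenced library of litter 1 had ida-1 at 50.69 CPM (others 34.35 to 37), and that of litter 2 had hsf-1 at 281.2 CPM (others 325.6 to 329). The silenced library of litter 3 had B0244.13 at 2.879 CPM and F54F7.12 at 1.308 CPM (others 0). The expressing library of litter 4 had his-58 (WBGene00001932) at 3.835 CPM (others 1.638 to 1.91).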

How the results depend on the processing

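Values that combine the block with another setting, the runs without 1 library for lists and shares, and the settings of the pairing check were chosen only after the data had been seen, the others before the data were examined. With every library thinned to the smallest total, 92 of the 121 blocked mRNA calls were kept. In counts simulated from the blocked model, 0% of mRNA changes of 1 on the log2 scale were recovered without the block.

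Where counts moved, the cause was not tested, except that no filter tests more genes and the runs without a litter use fewer samples. The mRNA count of 0 became 121 with the litter as a block, 3 with DESeq2 and 267 with DESeq2 and the block. The blocked 121 became 0 without the block, 344 with no filter and 265 at an adjusted p of 0.1, and without litter 1, 2, 3 or 4 it was 24, 52, 205 and 78. The small RNA count of 1 became 3 with the block, 51 with no filter, 2 with DESeq2, 226 with DESeq2 and the block and 0 with limma-voom, and ranged from 0 to 3 without single libraries (0 without expressing library 2). With the block it was 2, 4, 5 and 3 without litters 1 to 4. The blocked 3 became 1 without the block, 6 with DESeq2 size factors, 459 with no filter, 15 with the strict filter, 25 with limma-voom, 27 over protein-coding genes alone and 20 at an adjusted p of 0.1.

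Of 9 mRNA lists, 0 passed with an estimated correlation and 0 by fry, with or without the block, and 5 (without silenced library 1) to 13 (without silenced library 4) passed without single libraries or litters. For small RNA lists the 0 became 2 by fry with the block, 2 with DESeq2 size factors and the block, 5 without litter 3 with the block, and ranged from 0 to 6 (without silenced library 3) without single libraries. The correlation between assays (0.0125) ranged from -0.0205 without litter 4 to 0.0651 without litter 3. The lowest same-litter correlation of small RNA (0.215) was 0.375 with the strict filter. Shares of counts had 0 calls, and the alternatives for them say nothing about stability. The smallest p of exact sign flips within 4 litters is 0.125, and in the exact permutation tests, with all libraries or without 1, a single share could not pass adjustment.

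No called gene changed sign. Of 591 blocked values of the 50 named mRNA genes over the alternatives, 507 stayed on their side of the threshold, 76 lost the call (30 of them without the block) and 8 gained it. Of 249 blocked small RNA values 213 stayed, 7 lost and 27 gained it, and 2 uncalled values changed sign. Without the block, 890 of 1041 mRNA and 417 of 446 small RNA values stayed, 148 and 20 gained the call, 0 and 2 lost it, and 3 and 7 uncalled values changed sign. The calls for irg-4, hsp-70, F16B4.7, F08D12.3, F55G11.2 and nlp-30 were lost with upper-quartile scaling (adjusted p 0.0520 to 0.0608) and that for pck-1 with total-count scaling (0.0677). Besides the counts, genes and lists given, the block changed no other call.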

Other observations

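The test between short noncoding loci and tRNA genes and the choice of the genes set out here for litter 4 came only after the results were seen, and no test was run on litter 4 itself.

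Among genes with a col- symbol, 60 were tested in the mRNA libraries, 53 of them were higher in silenced sisters (median log2 change 0.58), and 15 rose and 0 fell within litters by edgeR. Of 6 genes with an mlc- symbol 3 rose, of 7 antimicrobial peptide genes with a cnc- symbol 2 fell, and of 67 genes with a clec- symbol 2 rose (39 higher, median 0.09). Of 111 F-box genes with an fbxa- or fbxb- symbol 87 were higher (median 0.27), 1 rose and 1 fell. These families were picked after the gene values were seen.

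The mRNA of litter 4 differed from that of the other litters in both sorts. Its expressing and silenced libraries also had more reads of low alignment quality (22.05% and 23.55%, against 11.35% to 13.53% in the other 6), fewer counts on genes (7254707 and 6184364, against 8965623 to 10433874) and fewer genes with a count (14138 and 14189, against 15232 to 15918). Library quality was therefore not separated from a difference between the animals. The yolk protein genes vit-2 and vit-5 stood at 58930 to 64170 and 57130 to 64270 CPM in its 2 libraries, against 4144 to 11480 and 2031 to 7562 CPM in the other 6. The basement membrane collagen gene let-2 stood at 668.3 to 869.1 CPM against 30.25 to 60.56, the myosin heavy chain gene unc-54 at 892.5 to 1426 against 46.61 to 102.8, and the chitin synthase gene chs-1 at 1852 to 2314 against 112.4 to 456.2. Lower in litter 4 were mbf-1 (153.8 to 321.6 CPM against 682.2 to 4863), clc-19 (31.57 to 57.89 against 171.3 to 907.2) and the small heat shock gene hsp-16.41 (311.4 to 365.7 against 972.7 to 4265). By list, 6 of 6 vitellogenins (median log2 difference 4.57) and 15 of 15 Argonaute genes (1.54) were higher, as were 47 of 55 small RNA machinery genes (0.93) and 21 of 28 oocyte genes (0.72). Of 77 ribosomal protein genes 0 were higher (-1.06) and of 28 histone genes 1 was (-0.95), and the adult cuticle (-0.66), body muscle (-0.50) and neuronal lists (-1.01) were lower.

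Small RNA counts of short noncoding loci varied more between libraries of the same sort than those of other classes. The median within-sort SD of log2 CPM was 0.959 over 318 short noncoding loci, 0.585 over 62 piRNA loci, 0.479 over 51 long noncoding and 0.375 over 8912 protein-coding genes.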
